A study of Rattus norvegicus with 2 samples.

How the data were processed

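Libraries were made from dental pulp of lower first molars of rats, 6 animals pooled per group, after selection of poly(A) RNA with oligo(dT) beads, and were sequenced as paired ends on an Illumina NovaSeq, per the labels' protocols and the series' design text. The labels' protocols state a larger RNA input per library than 6 animals would supply at the design text's yield per animal. These statements do not match. Whether libraries kept strand, how sleep deprivation was done and when tissue was taken are not given in the sources used here. Pooling averages the animals, so 1 animal with unusual tissue can move a pool.

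The deposited table gives FPKM and read counts per gene, both from the authors per the file headers. The count columns are headed only as counts, and those headings do not say whether the counts are raw. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR without saying what each did, and name the build hg38. That build is human, whereas all 21183 gene identifiers of the table are rat Ensembl identifiers. The table's own coordinates are printed as given. Of its genes 20586 had a count in either pool, 2284 carried an identifier in place of a symbol, and 148 symbols occurred more than once. Counts summed to 46152736 in the control pool and 47609602 in the sleep-deprived pool. The FPKM and the counts held the same information. This was checked over 12922 genes with at least 1 FPKM and more than 50 counts in both pools. There the log2 ratio of the FPKM differed from that of the deposited counts by a nearly constant offset (SD 0.00196). Pathway annotation columns of the table were not used here.

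From the deposited FPKM, log2((sleep-deprived + 1)/(control + 1)) was computed for 14032 genes with at least 1 FPKM in either pool, of which 12864 were protein-coding. With 1 library per group no test was made and no p-value is given. Genes were counted as higher or lower by size, at 2-fold or more on that scale. The plan, written before the data were examined, foresaw CPM in place of FPKM if the table held raw counts. The table held FPKM and counts, so FPKM was kept. CPM, with and without edgeR's TMM factors, was added as an alternative after seeing the data, with a pseudocount and a minimum of 1 CPM. For each named gene the exact Clopper-Pearson 95% interval of the CPM ratio was computed from both counts. It covers counting error only, and reads are not independent molecules. A count of 0 was set to a floor of 3 counts so that a fold could be given, which is not the bound of the counting interval.

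The comparison, size rule, gene lists, rule for naming genes and most of the other settings tried were fixed before the data were examined. Named genes were the 12 with the highest and the 12 with the lowest log2 ratio among genes with a proper symbol and at least 5 FPKM in the higher pool. From each list up to 4 measured members with the largest absolute log2 ratio and up to 2 with the highest mean FPKM could be named, as could all clock genes and Dspp, Dmp1, Nes, Col1a1, Nr3c1, Fkbp5 and Hspa5. Hspa5, a chaperone gene of the endoplasmic reticulum, stood at 106 and 104 FPKM. Some genes that this rule selects are not reported here. Any other gene named was chosen after its values were seen. Gene overlaps were taken from the table's coordinates and strands.

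The 47 lists covered clock, glucocorticoid, stress, immune, matrix, signalling, growth and metabolic pathways and markers of the cell types that pulp or neighbouring tissue could hold. A list's median log2 ratio over measured members was placed among medians of 10000 random lists of the same size, drawn within 20 bins of mean expression. Lists with fewer than 5 measured members were given values only. A list was set apart from random lists at percentile 2.5 or less, or 97.5 or more. Some genes belong to several lists, for example 5 of the glucocorticoid response genes and 7 of the odontoblast genes.

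Other settings set in advance were a pseudocount of 0.1, no minimum, a minimum of 5 FPKM, rescaling each pool to TPM with and without the 50 most abundant genes, division by the median ratio, and random lists without expression matching. Added after seeing the data were the CPM scales, random lists from named protein-coding genes with and without matching on length, and the glucocorticoid list without its clock genes.

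The procedure was tested on simulated data with the pools' own expression levels and library sizes, over 13877 genes. The size rule found 3 of 50 genes changed 1.5-fold, 11 of 50 changed 2-fold, 42 of 50 changed 3-fold and 49 of 50 changed 4-fold, and passed 5 of 13678 unchanged genes. Of 200 random lists of 16 genes 7 fell outside the central 95%, and 200 of 200 lists raised by 0.3 on the log2 scale were found. Besides counting error, the simulation gave each gene in each library random noise. That noise was normal, independent between genes and sized from the median absolute deviation of the 2 pools' own log2 ratios. The simulation therefore does not measure differences between animals, and its results are not those of counting error alone. Nor does it cover wider tails of the real ratios or lists whose genes vary together. Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16.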

Results

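Poly(A) RNA was sequenced from the dental pulp of 12 male Sprague-Dawley rats aged 8 weeks, to compare pulp of sleep-deprived animals with pulp of control animals. Pulp, the soft tissue inside the tooth that holds odontoblasts, fibroblasts, vessels, nerves and immune cells, came from the first molars of the lower jaw. RNA of 6 animals was combined in equal parts in each group, so the data were 1 control library and 1 sleep-deprived library. Gene counts totalled 46152736 in the control pool and 47609602 in the sleep-deprived pool. With 1 library per group there was no replicate check and no test. Values describe these 2 pools, and intervals cover counting error only, not differences between animals, dissections or library preparations. Expression is given as FPKM, fragment counts scaled for gene length and library size, and log2 ratios are log2 of (sleep-deprived FPKM + 1) over (control FPKM + 1), which understates the difference of weakly expressed genes.

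The pools were alike for most genes, and among the widest differences were those of Enam and Amelx, genes of the enamel matrix, which were lower in the sleep-deprived pool. Of 14032 genes with at least 1 FPKM in either pool, 73 were at least 2-fold higher and 99 at least 2-fold lower in the sleep-deprived pool, together 1.23%. Within 1.5-fold lay 94.8% of the genes. The median log2 ratio was 0.02, and Spearman's rho across genes, which are not independent replicates, was 0.978. The 95% counting interval lay wholly beyond 2-fold for 61 of the 73 and 85 of the 99. That interval is of the ratio of counts scaled to library size with nothing added, whereas the genes were called with 1 FPKM added. These counts depended on the scale: with a pseudocount of 0.1 FPKM they were 191 and 246, with a minimum of 5 FPKM they were 44 and 47, and on counts scaled to library size (CPM) they were 107 and 154.

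**Figure D1:**
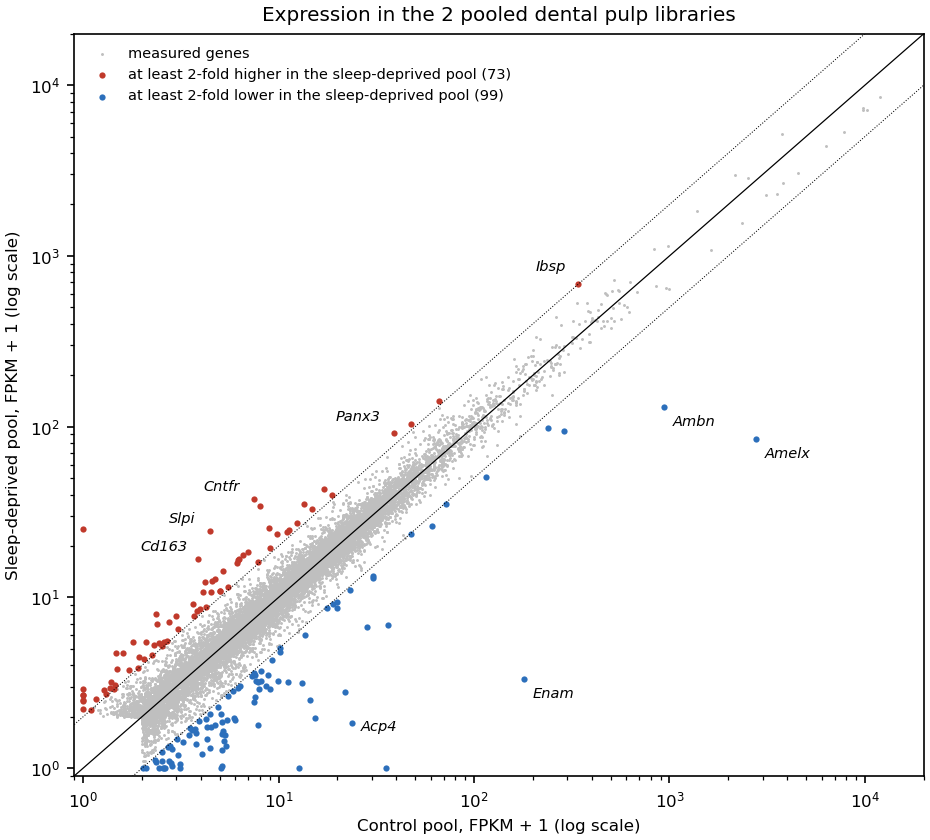
Each point is 1 of 14032 genes, with FPKM + 1 of the control pool on the horizontal log axis and FPKM + 1 of the sleep-deprived pool on the vertical log axis. Dotted lines mark 2-fold, with 73 genes at or above the upper line in red and 99 at or below the lower line in blue, where Amelx, Ambn and Enam lie far from the diagonal.

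Among named genes above 5 FPKM in the higher pool, the highest ratios belonged to Slpi, Cntfr, Cd163 and Dio3. Slpi, an inhibitor of leukocyte proteases, stood at 3.47 FPKM in the control pool and 23.4 in the sleep-deprived pool, 6.75-fold higher. Cntfr, the receptor subunit that binds ciliary neurotrophic factor, was 5.70-fold higher at 6.44 and 36.7 FPKM. Cd163, the macrophage receptor that takes up haemoglobin bound to haptoglobin, was 5.46-fold higher at 2.89 and 15.8 FPKM. Dio3, the deiodinase that inactivates thyroid hormone, was 4.76-fold higher at 7.04 and 33.5 FPKM. Their 95% counting intervals of the log2 CPM ratio ran from 2.41 to 3.06 for Slpi, 2.36 to 2.63 for Cntfr, 2.32 to 2.55 for Cd163 and 2.07 to 2.41 for Dio3. Hmox1, the haem oxygenase that breaks down haem, was 2.99-fold higher at 5.28 and 15.8 FPKM, and Mgst2, a microsomal glutathione transferase, was 4.30-fold higher at 1.40 and 6.02 FPKM. Pcsk1, a prohormone convertase, was 3.53-fold higher, the prostaglandin E2 receptor gene Ptger3 was 3.09-fold higher, the retinol carrier gene Rbp4 was 3.17-fold higher and Hpse, which encodes heparanase, was 3.23-fold higher. Hrct1 was 2.99-fold higher at 5.58 and 16.7 FPKM. Snord19b, a small nucleolar RNA lying inside the gene Gnl3, had a log2 ratio of 1.75 from 6 and 30 counts. Its log2 CPM ratio was 2.28 (95% counting interval 0.99 to 3.83), and 0.53 when 1 was added to its 0.130 and 0.630 CPM.

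Enamel matrix genes were far lower in the sleep-deprived pool. Enam, which encodes enamelin, was 77.3-fold lower, at 179.9 FPKM in the control pool and 2.33 in the sleep-deprived pool. Amelx, which encodes amelogenin, the main protein of forming enamel, was 33.4-fold lower at 2780.5 and 83.3 FPKM. Ambn, which encodes ameloblastin, was 7.30-fold lower at 938 and 128.5 FPKM. Together these 3 genes took 0.630% of control counts (95% exact binomial interval 0.628 to 0.633) and 0.0395% of sleep-deprived counts (0.0390 to 0.0401). The table places Enam on chromosome 14 at 19556729 to 19581425, Ambn beside it at 19601702 to 19614393, and Amelx on chromosome X at 25076362 to 25087660. The table does not name its build, and the only build in the submitters' processing notes, hg38, is a human build.

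Other genes with the 12 lowest ratios differed from 4.66-fold upward. Lamb3, which encodes a laminin chain of epithelial basement membrane, was 5.63-fold lower at 12.2 FPKM in the control pool and 2.16 in the sleep-deprived pool. Acp4, an acid phosphatase gene needed for enamel formation, was 26.9-fold lower at 22.7 and 0.847 FPKM. Plek2 was 11.7-fold lower, the calcium-binding protein gene Calb1 was 9.04-fold lower, Papln was 5.96-fold lower, Fam111a was 4.79-fold lower and Pstpip1 was 4.66-fold lower. Tubb2b, a beta-tubulin gene, had 884 counts in the control pool and 0 in the sleep-deprived pool, at least 304-fold lower in CPM when a count of 0 is set to a floor of 3 counts. Tubb2b overlaps Tubb2a on the same strand, so reads of these paralogs could be split between them. However, Tubb2a stood at 18.8 and 19.1 FPKM and did not gain as much as 50% of what Tubb2b lost. Of the 24 genes with the highest and lowest ratios, 23 stayed beyond 2-fold under every alternative scale and pseudocount tried, the exception being Snord19b.

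Epithelial markers were lower alongside the enamel genes. All 11 measured genes of the dental and oral epithelium list were lower, with a median log2 ratio of -0.68 (-0.35 without a minimum FPKM) and 1 gene past 2-fold. Krt5, a keratin of basal epithelium, stood at 32.9 and 18.1 FPKM, Krt17 at 11.5 and 5.28, the adhesion gene Cdh1 at 2.90 and 1.204, the desmosome gene Pkp1 at 20.2 and 13.3, and Perp, past 2-fold, at 9.22 and 4.07. Of 9 measured genes in the ameloblast and enamel list, 6 were lower, 3 of them past 2-fold (Enam, Amelx and Ambn), and the median was -0.33. Slc24a4, an ion exchanger gene of enamel-forming cells, went the other way at 1.86 and 3.91 FPKM. To place each list, its median was ranked among the medians of 10000 random lists of the same size and expression. The epithelium list lay at percentile 0 and the ameloblast list at percentile 0.055. With FPKM rescaled to an equal total in each pool (TPM) the ameloblast median was -0.13, inside the central 95% of random lists. It was -0.17 without a minimum and -1.71 with a minimum of 5 FPKM. The rescaling to TPM also makes the pseudocount and minimum smaller against the values, so weakly expressed members can enter the median.

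Across the 47 gene lists fixed before the data were examined, 40 had at least 5 measured genes and were ranked in this way. Of these, 17 lay above the central 95% of random lists, 4 below and 19 within, where 2 outside would be expected for lists of unrelated genes. Genes of a list vary together, so their medians spread more widely than those of random lists, and the percentiles describe these 2 libraries only. Housekeeping reference genes were themselves at 0.22, so a list median of about that size does not set a list apart from them.

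**Figure D2:**
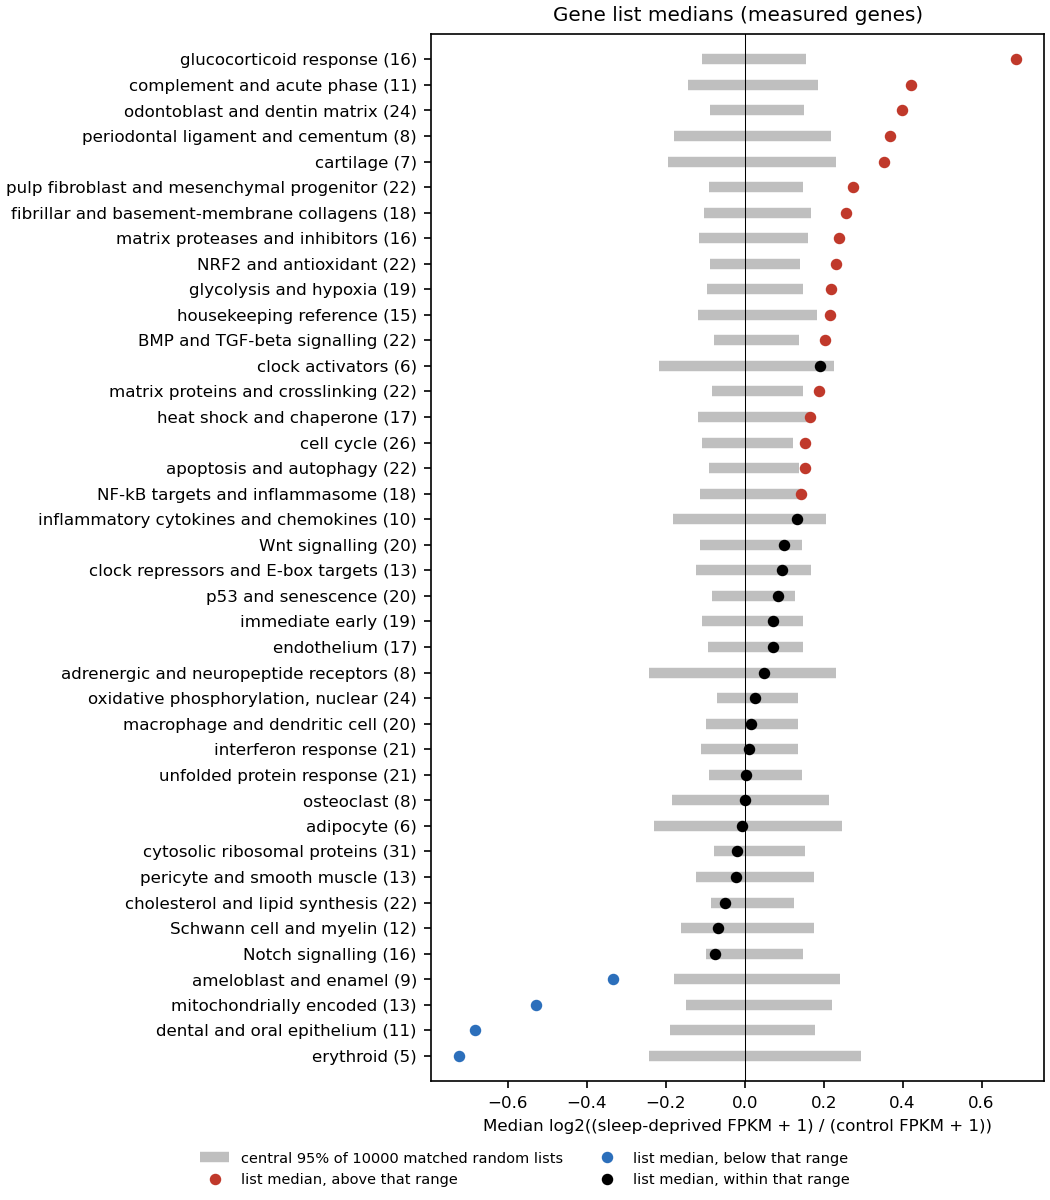
Points are the median log2 ratios of 40 gene lists, with the number of measured genes in parentheses, and grey bars are the central 95% of 10000 random lists matched on size and expression. The glucocorticoid response list lies at 0.69, and the erythroid, epithelium, mitochondrial and ameloblast lists lie below the grey bars.

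Glucocorticoid response genes were higher as a group in the sleep-deprived pool. Of 16 measured genes 15 were higher and 4 were past 2-fold, with a median log2 ratio of 0.69 at percentile 100. Per1, a clock gene that glucocorticoids also induce, stood at 12.5 and 34.2 FPKM. Errfi1, a feedback inhibitor of EGF receptor signalling, stood at 6.01 and 17.3, the transcription factor gene Cebpd at 10.02 and 23.2, and the metallothionein gene Mt2A at 0.594 and 3.73 FPKM. The most abundant members were Sgk1, a kinase gene, at 69.3 and 87.8 FPKM, and Ddit4, an inhibitor of mTOR signalling, at 57.4 and 83.9. Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 7.90 and 10.6 FPKM, and the receptor gene Nr3c1 itself at 4.39 and 4.54 FPKM. Without Per1 and Tsc22d3, which the clock lists also hold, the median of 14 genes was 0.66 at percentile 100, a comparison added after seeing the data.

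Most core clock genes other than Per1 were close in the pools. The 6 measured genes of the clock activator list, which also holds the repressor genes Cry1 and Nfil3, had a median log2 ratio of 0.19 at percentile 95.1, with Bmal1 at 11.5 and 12.6 FPKM, Clock at 11.2 and 11.6, and Cry1 at 3.54 and 5.03. That list passed above the central 95% of random lists with a pseudocount of 0.1 (median 0.28) and with TPM (0.34). The 13 measured repressors and E-box targets had a median of 0.10 at percentile 83.1, and 11 of them were higher. Per2 stood at 19.1 and 19.3 FPKM, Per3 at 28.9 and 30.1, and Nr1d1, which encodes the repressor REV-ERB alpha, at 35.5 and 36.5. Dbp, an output gene of the clock, was lower at 40.7 and 28.3 FPKM. The hour of tissue collection is not given in the sources used here. Immediate early genes, which respond within minutes to stimulation, had a median of 0.07 over 19 genes at percentile 78.7, with Fosl2 at 19.5 and 31.5 FPKM and Fos at 2.58 and 4.01.

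Odontoblast and dentin matrix genes were higher as a group in the sleep-deprived pool, which also had lower epithelial and haemoglobin transcripts. Of 24 measured genes 20 were higher and 2 were past 2-fold, and the median log2 ratio was 0.40 at percentile 100. Marker lists of periodontal ligament and cementum and of cartilage were higher by about as much, with medians of 0.37 and 0.35 (0.14 for cartilage without a minimum). Panx3, a channel gene of mineralising cells, stood at 37.9 and 90.4 FPKM, and Ibsp, which encodes bone sialoprotein, at 337 and 687. Dmp1, a gene of mineralised matrix, was 1.67-fold higher at 263 and 438 FPKM, and Dspp, which encodes the main non-collagen proteins of dentin, was 1.31-fold higher at 831 and 1090.4. Col1a1, the chief collagen gene of dentin and pulp, stood at 3766 and 5171 FPKM, and Bmp2 at 28.2 and 48.6. Nes, an intermediate filament gene of odontoblasts, was slightly lower at 246 and 223 FPKM. The pulp fibroblast and mesenchymal progenitor list had 16 of 22 genes higher and a median of 0.27 at percentile 100. Its proteoglycan genes Dcn and Lum stood at 159 and 247 FPKM and at 376 and 530.3, while the chemokine gene Cxcl14 was lower at 109 and 74.6.

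**Figure D3:**
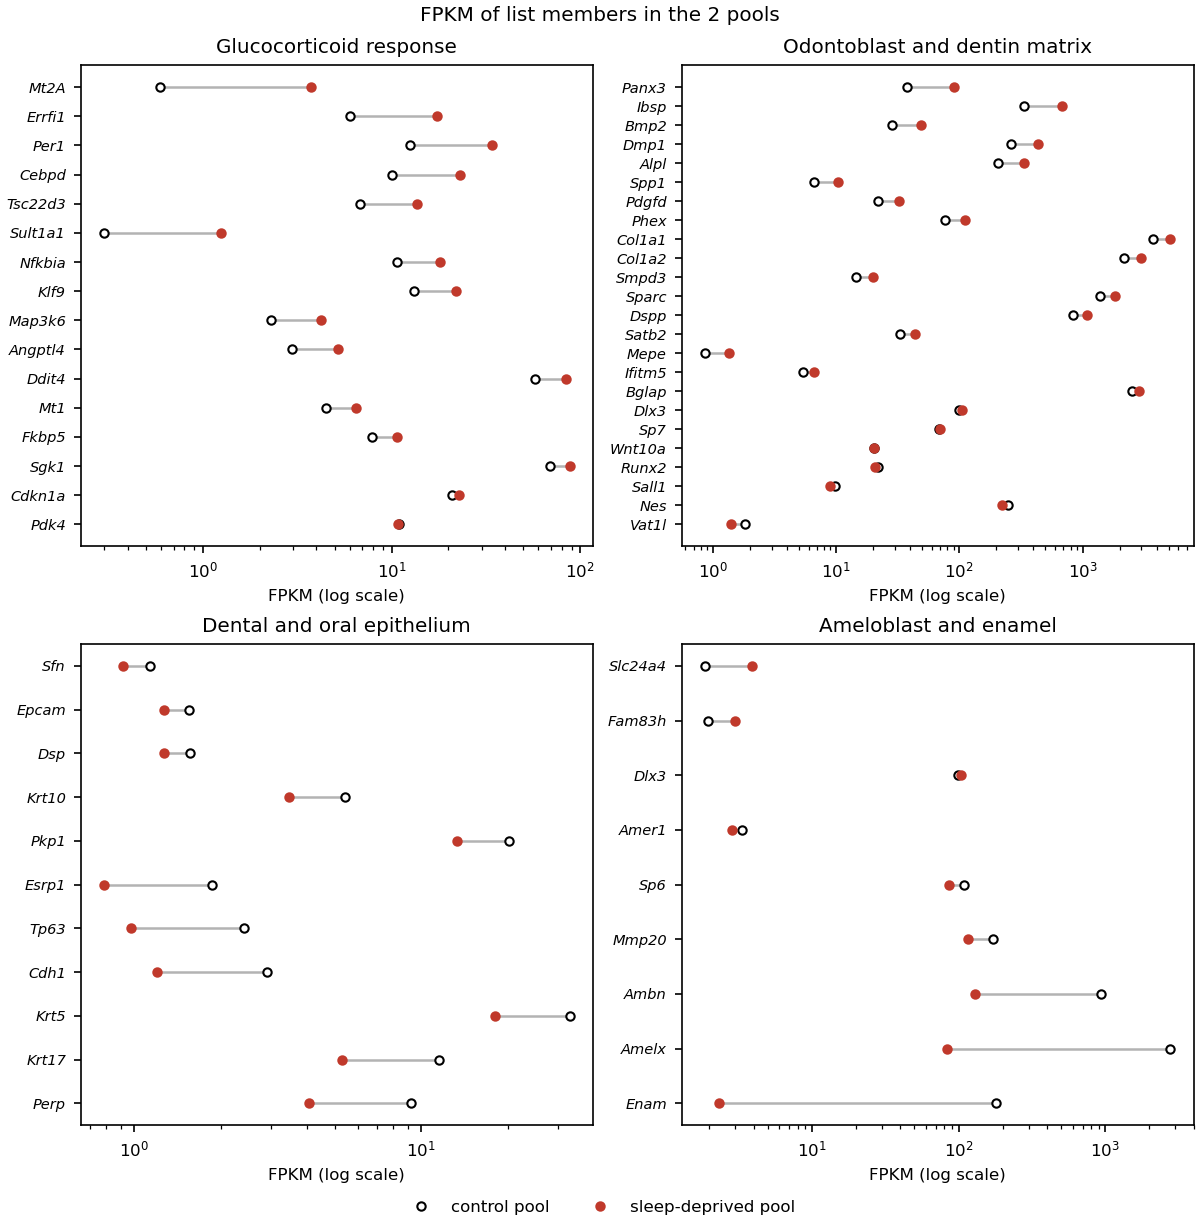
FPKM on a log axis of each measured member of 4 gene lists, with open circles for the control pool and red circles for the sleep-deprived pool. Of the glucocorticoid response genes 15 of 16 are higher in the sleep-deprived pool, and of the epithelium genes all 11 are lower.

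Extracellular matrix genes were mostly higher, with list medians of about the size of the housekeeping median of 0.22. Fibrillar and basement-membrane collagens had 13 of 18 genes higher with a median of 0.26 at percentile 99.9, although Col15a1 was lower at 5.30 and 2.47 FPKM. Matrix proteins and crosslinking enzymes had 16 of 22 genes higher with a median of 0.19 at percentile 99.5, led by Ccn1, a matricellular signalling gene, at 6.80 and 15.2 FPKM. Matrix proteases and inhibitors had 11 of 16 genes higher with a median of 0.24 at percentile 99.9. The membrane protease gene Mmp16 stood at 18.0 and 32.7 FPKM and the inhibitor gene Timp3 at 67.2 and 116, while the urokinase gene Plau was lower at 3.97 and 1.97.

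Immune lists were mixed. The macrophage and dendritic cell list had 10 of 20 genes higher and a median log2 ratio of 0.02 at percentile 45.3. Within it Cd163, C1qb and Mrc1 were higher, the latter pair at 24.4 and 46.2 FPKM and at 9.42 and 16.6, while Adgre1, which encodes the F4/80 antigen, was lower at 6.15 and 3.08. Complement and acute phase genes were higher in all 11 measured members, with a median of 0.42 at percentile 100. Ptx3, a soluble pattern recognition gene, stood at 8.03 and 18.4 FPKM and the complement protease gene C1r at 46.2 and 72.1. Among 22 NRF2 and antioxidant genes 17 were higher, with a median of 0.23 at percentile 99.97 (0.35 with TPM). Hmox1 led, Nqo1 stood at 2.43 and 4.97 FPKM, and the ferritin heavy chain gene Fth1 at 464 and 602.

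Inflammatory cytokine and adhesion genes lay inside the central 95% of random lists. Only 10 of that list were measured, 5 were higher and 5 lower, and the median was 0.13 at percentile 89.2 (0.01 without a minimum, 0.21 with TPM), with Icam1 at 7.74 and 12.2 FPKM and Tgfb1 at 60.9 and 86.5. NF-kB targets and inflammasome genes had a median of 0.14 over 18 genes at percentile 97.6 (0.24 with TPM), with the feedback inhibitor gene Nfkbia at 10.7 and 18.1 FPKM and Nfkbiz at 3.73 and 7.33. That list lay at percentile 96.9 among named protein-coding random lists, inside the central 95%. Interferon response genes had a median of 0.01 over 21 genes at percentile 46.5, with Mx2 lower at 5.36 and 3.004 FPKM and the immunoproteasome gene Psmb8 higher at 8.63 and 14.3. Markers of other leukocytes were too few to rank. The neutrophil list had 4 measured genes with a median of 0.45, among them the calprotectin genes S100a8 at 2.05 and 4.22 FPKM and S100a9 at 0.792 and 4.46. The T and NK cell list had 1 measured gene, Nkg7, at 0.482 and 1.00 FPKM. The B and plasma cell list had 3 with a median of 0.06, including the immunoglobulin gene Ighm at 3.51 and 0.747. The mast cell list had 2 with a median of 0.06, Kit at 55.1 and 64.0 FPKM and Gata2 at 2.17 and 1.98.

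Blood and mitochondrial transcripts were lower in the sleep-deprived pool. All 5 measured erythroid genes were lower, with a median log2 ratio of -0.72 at percentile 0 (-0.16 without a minimum, -0.46 with TPM, -0.49 with CPM), and the globin gene Hbb stood at 114.6 and 49.8 FPKM and Hba-a1 at 115.5 and 66.0. All 13 protein-coding genes of the mitochondrial genome were lower, with a median of -0.53 at percentile 0. Among them Mt-nd5, a subunit gene of respiratory complex I, stood at 2338 and 1564 FPKM. The mitochondrial chromosome took 7.79% of counts in the control pool (95% exact binomial interval 7.79 to 7.80) and 5.40% in the sleep-deprived pool (5.39 to 5.41). Nuclear genes of oxidative phosphorylation had a median of 0.03 over 24 genes at percentile 42.2, with the ATP synthase gene Atp5f1b at 203 and 229 FPKM. Cytosolic ribosomal protein genes had a median of -0.02 over 31 genes at percentile 15.6 (0.05 with TPM), with Rpl4 at 586 and 516 FPKM and Rplp0 at 429 and 480. Housekeeping reference genes had a median of 0.22 over 15 genes at percentile 99.0, including the cytoskeletal gene Actb at 517 and 724 FPKM and the elongation factor gene Eef1a1 at 983 and 1143.

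Vessel and Schwann cell lists lay inside the central 95% of random lists. Endothelial genes had a median log2 ratio of 0.07 over 17 genes at percentile 77.6, with Plvap, a gene of fenestrated endothelium, at 27.0 and 36.9 FPKM and Emcn at 28.7 and 22.2. Pericyte and smooth muscle genes had a median of -0.02 over 13 genes at percentile 23.7, with Rgs5 at 98.7 and 86.5 FPKM and Acta2 at 36.8 and 38.8. Of 12 Schwann cell and myelin genes 9 were lower, with a median of -0.07 at percentile 19.3. Among them the myelin gene Mbp stood at 1.94 and 0.961 FPKM, and the neurotrophin receptor gene Ngfr at 7.46 and 3.97. The neuron and axon list had 4 measured genes with a median of 0.17, including the axonal growth gene Gap43 at 13.3 and 17.7 FPKM and the heat-sensing channel gene Trpv1 at 2.23 and 1.38.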

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

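The CPM scales, the 2 kinds of random list from named protein-coding genes and the glucocorticoid list without clock genes were chosen after seeing the data, as were the limits for calling the all-gene median and the correlation across genes moved. No paired analysis was possible because each group is 1 pooled library, and no library could be left out. No direction reversed among the list medians outside the central 95% of random lists, nor among the 24 genes of highest or lowest ratio. Against 73 genes higher and 99 lower, the counts were 191 and 246 with a pseudocount of 0.1, 44 and 47 with a minimum of 5 FPKM, 274 and 299 with TPM, 359 and 522 with TPM without the 50 most abundant genes, and 107 and 154 with CPM, with or without TMM factors. FPKM summed to 332660 and 315910, so rescaling to 1000000 made the same pseudocount and minimum smaller against the values, which by itself adds weakly expressed genes. Without a minimum they were 73 and 99, and after division by the median ratio 71 and 103. Spearman's rho was 0.962 with a minimum of 5 FPKM, a narrower range of expression, and 0.986 with either CPM scale. Clock activators passed above the central 95% of random lists with a pseudocount of 0.1 (median 0.28) and with TPM (0.34). The ameloblast median with TPM was -0.13, inside the central 95%. The heat shock list fell inside it with a pseudocount of 0.1 (0.17), a minimum of 5 FPKM (0.13), TPM (0.24), TPM without the 50 genes (0.13), the median ratio (0.14), CPM (0.15 with and without TMM) and both kinds of protein-coding random list (0.16). NF-kB targets did so with unmatched and both protein-coding random lists (0.14), and cartilage without a minimum (0.14). The cause of the changes in lists was not tested. Several list medians near 0, all inside the central 95%, took the other sign under some settings, among them ribosomal proteins (0.05 with TPM). Snord19b, at 6 and 30 counts, was under 2-fold with 1 added to CPM (0.53 with and without TMM), an addition larger than its CPM of 0.130 and 0.630. The other 646 values under these settings stayed within the limits used, which for a count of genes or lists allowed a difference of up to 1.5-fold. Some of them could not differ, since a minimum FPKM leaves the ratio of a single gene as it was.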

Other observations

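Tests chosen only after their own result or closely related values were seen were those of reads overlapping the enamel genes, of transcription in pulp cells, of clock phase and of gene length, and all patterns weighed were picked after the results were seen. The extra epithelium and glucocorticoid lists were written after their patterns were seen but before their members' values were, and the overlap share was prompted by single genes such as Tubb2b.

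Signalling and growth lists were mixed. BMP and TGF-beta genes had 16 of 22 members higher with a median log2 ratio of 0.20 at percentile 99.8, and the inhibitor gene Nog stood at 2.32 and 3.85 FPKM while Tgfb3 was lower at 207 and 163. Wnt genes had a median of 0.10 over 20 members at percentile 89.2, with the receptor gene Fzd1 at 7.68 and 13.5 FPKM and Wnt4 at 1.61 and 0.707. Of 16 Notch genes 10 were lower, with a median of -0.08 at percentile 5.28 and the ligand gene Jag2 at 17.8 and 11.97 FPKM. Cell cycle genes had 19 of 26 members higher with a median of 0.15 at percentile 99.3 (0.27 with a minimum of 5 FPKM, 0.26 with TPM), including the mitotic kinase gene Aurkb at 6.28 and 10.4 FPKM. The p53 and senescence list had a median of 0.08 over 20 genes at percentile 85.5, with Gadd45b at 9.83 and 15.8 FPKM. Apoptosis and autophagy genes had a median of 0.15 over 22 genes at percentile 98.6 (0.23 with TPM), with the autophagy receptor gene Sqstm1 at 93.0 and 114 FPKM. The 4 measured histone genes had a median of -0.01, with H1f0 at 59.6 and 65.5 FPKM.

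Stress and metabolic lists were mixed. Glycolysis and hypoxia genes had 13 of 19 members higher with a median of 0.22 at percentile 99.9. Adm, which encodes the vasodilator adrenomedullin, stood at 2.94 and 7.56 FPKM and the lactate dehydrogenase gene Ldha at 18.1 and 35.1, while Vegfa was lower at 186 and 157. Unfolded protein response genes had a median of 0.00 over 21 members at percentile 31.9, with Ddit3 at 19.8 and 13.0 FPKM. Heat shock genes had a median of 0.16 over 17 members at percentile 97.7, with Hspb1 at 22.2 and 32.0 FPKM, a placing that most alternatives ended. Cholesterol and lipid synthesis genes had a median of -0.05 over 22 members at percentile 9.46, with Srebf2, a master regulator of sterol synthesis, at 21.5 and 16.6 FPKM. Adrenergic and neuropeptide receptors had a median of 0.05 over 8 members at percentile 68.6, with the receptor component gene Calcrl at 4.77 and 5.03 FPKM.

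Besides the lower epithelium and ameloblast lists, periodontal ligament and cartilage lists were higher, and osteoclast, adipocyte and skeletal muscle lists were near 0. Periodontal ligament and cementum genes had 7 of 8 members higher with a median of 0.37 at percentile 99.9, and Postn stood at 24.8 and 36.1 FPKM and Aspn at 0.383 and 1.62. Cartilage genes had 5 of 7 higher with a median of 0.35 at percentile 99.9 (0.14, inside the central 95%, without a minimum), although the most abundant, Col11a2, was lower at 620.5 and 466 FPKM. Osteoclast genes had a median of 0.00 over 8 members at percentile 43.4, with the collagenase gene Ctsk at 55.0 and 85.2 FPKM. Adipocyte genes had a median of -0.01 over 6 members at percentile 45.0, with Pparg at 2.31 and 3.85 FPKM. The skeletal muscle list had 2 measured genes with a median of 0.01, and Tnnt3 stood at 7.24 and 6.94 FPKM.

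Enam, Amelx and Ambn were far lower in the sleep-deprived pool, and an exchange of reads with overlapping genes is argued against: 0 genes of the table overlap Enam or Ambn, and the 1 gene overlapping Amelx, on the opposite strand, had 135 and 80 counts and gained 0% of what Amelx lost. A candidate explanation is that the control pool held more dental epithelium, for example from another tooth's enamel organ in 1 or more animals. In an extra list of epithelial genes 15 of 18 measured members were lower, with a median log2 ratio of -0.30 at percentile 0.02 and the integrin gene Itgb6 at 4.23 and 0.432 FPKM. Epithelial markers differed far less than Enam or Amelx. The enamel protease gene Mmp20, picked after its values were seen, stood at 170.3 and 115 FPKM. A uniform loss of epithelium would not give these values if all these transcripts came from epithelium alone. Pooled pulp cannot show whether they did, so these values do not decide the question. Lower transcription in the pulp's own cells after sleep deprivation cannot be told apart from more epithelium in the control pool with 1 library per group.

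The higher glucocorticoid response genes may reflect a class-wide difference in glucocorticoid targets. An extra list of such targets, sharing no gene with the fixed lists, had 20 of 21 members higher, a median of 0.22 at percentile 99.97 and Bcl6, a transcriptional repressor gene, at 2.38 and 5.22 FPKM. Gene length and annotation class are argued against as causes, since the fixed list stayed at percentile 100 among protein-coding lists matched on expression and length. A different clock phase cannot be told apart from this, since the median absolute log2 ratio of 17 clock genes outside the list, 0.13, lay inside the central 95% of random lists at percentile 33.75, while Dbp was lower at 40.7 and 28.3 FPKM and Cry1 higher at 3.54 and 5.03. Stress of handling, dissection order and hormone levels are not given in the sources used here, 17 of 40 lists lay above the central 95%, and housekeeping genes also had a median of 0.22, so the extra list does not set glucocorticoid targets apart from these.

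Some large single-gene differences may come from how reads were assigned between overlapping genes. Of the 172 genes past 2-fold, 30 (17.4%) overlapped a gene on the same strand, at percentile 99.87 of matched random gene sets, whose mean was 9.85% (central 95% 5.81 to 14.5). For 12 genes the overlapping partners differed the other way by at least 50% of the change, as with Dohh at 7.998 and 1.91 FPKM and Smim44 at 1.10 and 4.47. How often this holds for overlapping genes under 2-fold was not counted, so the 12 alone do not show an exchange of reads. Tubb2b was not among the 12. Overlaps on opposite strands were left out of this share, and the strandedness of the libraries is not given in the sources used here.

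In 8 genes 1 pool had 0 counts and the other at least 100, 6 of them at 0 in the sleep-deprived pool. The noncoding gene ENSRNOG00000063951 had 6287 control and 0 sleep-deprived counts. ENSRNOG00000063350, which covers nearly the same interval on the opposite strand, had 6288 and 12111. Control counts were thus nearly equal between these overlapping genes, and the partner was higher where the other stood at 0. That 0 therefore does not show a loss of RNA from the interval, and read assignment between these genes was not tested. A pseudogene on chromosome 7, ENSRNOG00000065596, had 0 control and 365 sleep-deprived counts. These genes were named after their values were seen.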
